A study of Mus musculus with 18 samples.

How the data were processed

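Bulk RNA sequencing libraries were made from total RNA of basal, luminal progenitor (LP) and mature luminal (ML) cells sorted from mammary glands of 14-week-old female mice, 3 mice per genotype, per the labels. The 18 libraries form 6 groups of 3. The genotype label separates Brca2 knockout (KO) from wildtype (WT) mice. Sample names give MMTVcre, Brca2 and Trp53 for the KO mice alone. They say knockdown where the genotype label says knockout, so groups follow the genotype label. The strain label, MMTVcre Brca2(fl/fl) Trp53(fl/+), reads the same for all 18 libraries, WT included. Deletion of both copies of Brca2 and 1 copy of Trp53 in KO is read from that label. It leaves open whether the WT mice carried the transgene. Whether they were littermates is not given in the sources used here, so strain background and genotype cannot be separated.

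The deposited values are whole-number read counts per gene, made by the authors with featureCounts on the mm10 assembly, per the submitters' processing notes. Tool versions, the aligner, the annotation and the strand setting are not given in the sources used here. The series-wide table equalled the 18 single-library files, and 0 of its columns lacked a sample. Of 27179 gene identifiers, 25275 matched a gene symbol in the mouse reference tables and 1904 did not (1.6% of all counts). No replicate of a group repeated another of that group: the chi-square per degree of freedom was 23.9 to 220.4, and pairs across groups were not compared.

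Total counts (M) were 14.15 to 39.19 in basal KO, 12.08 to 33.49 in basal WT, 22.42 to 32.72 in LP KO, 9.29 to 16.17 in LP WT, 8.76 to 30.55 in ML KO and 5.97 to 20.33 in ML WT. The 10 most abundant genes held 4.83% to 8.81% of a library. Genes were filtered with edgeR's filterByExpr, which left 16466, and scaled with TMM (factors 0.832 to 1.19). edgeR 4.0.16 quasi-likelihood fits in R 4.3.3 used all 18 libraries with 1 mean per group. The biological coefficient of variation was 33.3%. The contrasts were KO against WT in each population, the difference of these effects between populations (interaction), and the WT populations against each other. P-values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05. The first 2 principal components of log CPM held 49.6% and 19.1% of the variance.

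Choices made before the data were examined were the contrasts, the tests, 36 gene lists and the rule for naming genes. The rule took Brca2 and Trp53, and the 10 largest rises and falls per population with a mean of at least 2 CPM and no overlap of the genotypes, without predicted, olfactory or antigen receptor genes. It also took up to 4 members of lowest p per list described, 5 genes of lowest p per interaction, and up to 4 per identity list between WT populations. Genes named outside it were chosen after their values were seen: the other basal identity genes compared between ML KO and basal KO, Acta2, and Cdkn2a in basal cells and LP. Lists with at least 5 measured genes (35) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it. Counts "adjusted over the list alone" use only the members' p-values. Where all WT libraries had 0 counts, folds were computed against a floor of 3 counts over the group.

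The edgeR test of each contrast was run on simulated counts with known changes. DESeq2 and limma voom were simulated for KO against WT only. The list tests were simulated in LP only, and a fit with the mouse as a block for the interaction of LP and basal cells only. The other alternatives given below were not simulated. With 200 of 16466 genes changed, edgeR recovered 74.2%, 47% and 56.1% of the 4-fold changes in basal, LP and ML KO against WT, 7.5%, 14.9% and 10.4% of the 2-fold changes and 1.5%, 0% and 0% of the 1.5-fold changes. Of its calls 16.7%, 22.6% and 13.7% were false, above the nominal 5%, and for DESeq2 19.3%, 26.5% and 25%. The fixed test was kept. Further simulations, added after this, used 5 seeds. With 200 changed genes 17%, 13.7% and 9.3% of calls were false, and with 2000 changed genes 7.7%, 6% and 6.7%. In libraries with no change, the genes lying under the p-values that bounded the real calls came to 9.6%, 6% and 5.8% of the real counts in basal, LP and ML. False calls in the simulated interactions were 5.4% to 7.7% and in the WT contrasts 4.4% to 5.4%. Simulated libraries were drawn independently, without a mouse effect. Real libraries of the same mouse were correlated (given below), which these shares of false calls leave out.

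Replicate numbers within a genotype mark the same mouse across populations, per the labels. Deviations from the group means of same-mouse libraries correlated at 0.095 to 0.33, over 0.1 in 17 of 18 pairs. A fit with the mouse as a block is therefore given beside the interaction counts. Across genotypes a number is shared by different mice only. The alternatives tried were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom with the mouse as a random effect, fits of 1 population's 6 libraries, replicate blocks, and leaving out each library or mouse. After the data had been seen, thinning of every library to the shallowest total and removal of per-library trends on GC content and exon length (GC known for 95.1% of tested genes) were added. Reference coordinates are those of GRCm38, the assembly named mm10. Chromosome shifts are medians of log2 fold changes against the autosomal median. Results for 1 item withheld for evaluation are not reported here.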

Results

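Messenger RNA was measured in 3 epithelial cell populations sorted from the mammary glands of 14-week-old female mice. The populations were basal cells, the contractile outer layer of the ducts, and 2 kinds of inner luminal cell. Luminal progenitors (LP) give rise to the milk-secreting alveolar cells, and mature luminal (ML) cells carry the hormone receptors. 3 mice carried the MMTV-cre transgene, which is active in mammary epithelium, with both copies of Brca2 and 1 copy of Trp53 deleted (KO). 3 mice were wildtype (WT). The copy numbers are taken from the strain label, which reads the same for the WT libraries. Each mouse gave 1 library per population, so that 18 libraries fell into 6 groups of 3. Total counts per library ran from 5.97 M to 39.19 M. They were 9.29 M to 16.17 M in LP WT and 22.42 M to 32.72 M in LP KO, so the LP groups did not overlap in depth. Levels are in CPM after TMM scaling, given as mean ± SD over n = 3 mice, with KO first. Adjusted p-values are from edgeR's quasi-likelihood test over 16466 genes.

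Trp53, which encodes the p53 tumour suppressor (gene 22059, chromosome 11, 69580348 to 69591873 in the mm10 assembly), was lower in KO than in WT in each population. It stood at 8.002 ± 0.934 against 96.7 ± 46.5 CPM in LP, a 12.1-fold lower level (log2 fold change -3.60, SE 0.35, adjusted p = 5.3e-06). In basal cells it stood at 22.7 ± 11.6 against 74.9 ± 16.2 CPM (log2 fold change -1.72, SE 0.33, adjusted p = 0.0034). In ML cells it stood at 15.2 ± 1.72 against 45.3 ± 5.09 CPM (log2 fold change -1.57, SE 0.33, adjusted p = 0.0023). All 3 KO libraries lay below all 3 WT libraries in each population. The fall in LP was steeper than that in ML by a log2 difference of -2.03 (SE 0.46, edgeR interaction adjusted p = 0.0098). That call was lost without WT mouse 3 (log2 difference -1.47, adjusted p = 0.085, range over 11 settings added after seeing the data 9.3e-04 to 0.085). Against basal cells the difference was -1.88 (SE 0.46, adjusted p = 0.0503), just outside the threshold of 0.05 (0.024 with the mouse as a block, range 0.0084 to 0.19), and between ML and basal cells it was 0.14 (SE 0.46, adjusted p = 0.92).

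Brca2, which encodes a mediator of homologous recombination (gene 12190, chromosome 5, 150522297 to 150570147), did not differ detectably between the genotypes in summed counts. It stood at 7.57 ± 2.86 against 12.996 ± 7.58 CPM in basal cells (log2 fold change -0.74, SE 0.49, adjusted p = 0.68) and at 18.5 ± 7.38 against 25.9 ± 9.61 CPM in LP (log2 fold change -0.50, SE 0.47, adjusted p = 0.51). In ML it stood at 11.2 ± 4.07 against 9.46 ± 5.63 CPM (log2 fold change 0.19, SE 0.49, adjusted p = 0.84). The deposited value is 1 count over the whole gene, and the sources used here do not give the exons that were deleted. Reads from exons outside a deletion are counted with the rest, so this value does not test the Brca2 label.

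**Figure D1:**
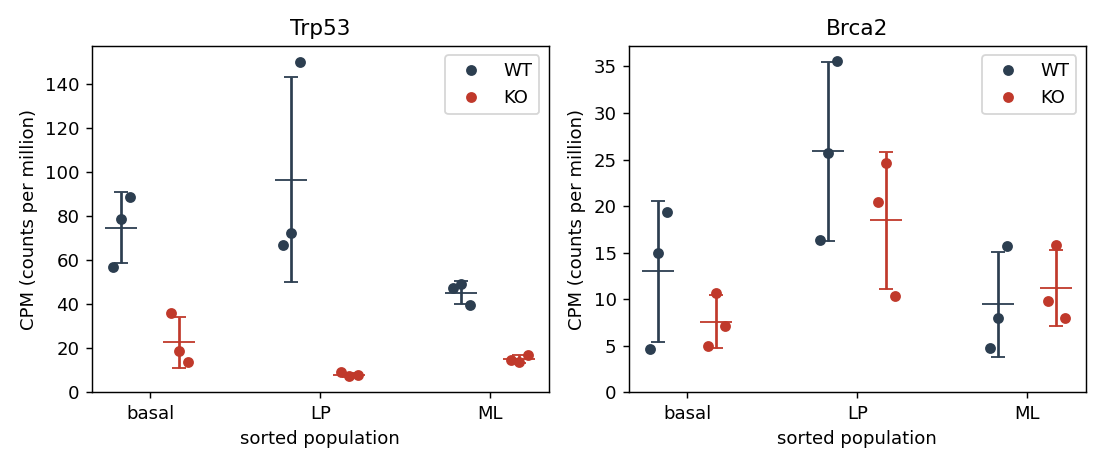
Trp53 and Brca2 levels (CPM, vertical axis) in basal, LP and ML cells; points are single mice, horizontal marks the mean and bars the SD of 3 mice. Trp53 stood at 8.002 ± 0.934 CPM in LP KO and 96.7 ± 46.5 CPM in LP WT, while the Brca2 points of the 2 genotypes overlap in each population.

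The WT populations were compared with each other to place the sorts. Krt5, a keratin of basal cells, stood at 1874 ± 29.2 CPM in basal cells, 2.60 ± 0.838 in LP and 2.64 ± 0.788 in ML. Kit, a receptor found on luminal progenitors, stood at 726 ± 203 CPM in LP, 11.8 ± 1.37 in ML and 2.16 ± 0.738 in basal cells. Foxa1, a cofactor of the estrogen receptor, rose from 37.8 ± 7.73 CPM in LP to 355 ± 63.2 in ML. The prolactin receptor Prlr stood at 5143 ± 391 CPM in ML, 468 ± 88.6 in LP and 4.06 ± 1.95 in basal cells. All 22 measured genes of the basal identity list were lower in LP and in ML than in basal cells (camera adjusted p = 6.7e-47 and 2.2e-38; 22 and 22 adjusted over the list alone). Of 19 luminal progenitor genes, 18 were higher and 1 lower in LP than in ML (camera adjusted p = 4.3e-19; 18 and 1 adjusted over the list alone). Of 20 mature luminal genes, 18 were higher and 2 lower in ML than in basal cells (camera adjusted p = 1.2e-10; 18 and 2 adjusted over the list alone), and these 4 tests also passed with an estimated correlation (adjusted p = 2.7e-05 and 9.8e-05 for the basal, 0.010 for the progenitor and 0.019 for the mature luminal list). Between LP and ML, 14 mature luminal genes were higher in ML and 2 higher in LP (16 and 2 adjusted over the list alone, camera adjusted p = 1.2e-08; adjusted p = 0.063 with an estimated correlation). Counting all genes, 6106 differed between LP and basal cells, 5548 between LP and ML, and 8981 between ML and basal cells. Without WT replicate 2 the counts for LP against basal cells and against ML were 3973 and 3443.

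In basal cells, the comparison of KO with WT asked what the deletion changed in the outer layer, and cell cycle genes were the list of lowest p among those that rose. Cdk1, the kinase that drives entry into mitosis, stood at 23.2 ± 8.01 against 0.363 ± 0.175 CPM (log2 fold change 5.82, SE 0.42, adjusted p = 4.5e-08). The spindle checkpoint kinase Bub1 stood at 13.8 ± 5.83 against 0.0771 ± 0.0923 CPM (adjusted p = 4.5e-08), and the spindle assembly factor Tpx2 at 38.3 ± 13.6 against 0.628 ± 0.360 CPM. Of 36 measured cell cycle genes 25 rose and 0 fell, with 29 rising when adjusted over the list alone (camera adjusted p = 2.1e-72; adjusted p = 0.0030 with an estimated correlation). Interferon-stimulated genes rose alongside. Of 34 measured members 27 rose and 0 fell, 32 adjusted over the list alone (camera adjusted p = 6.0e-63; adjusted p = 0.017 with an estimated correlation). The chemokine Cxcl10 stood at 144 ± 44.6 against 6.31 ± 2.91 CPM (log2 fold change 4.46, SE 0.43, adjusted p = 2.9e-06), the 2-5 oligoadenylate synthetase-like Oasl1 at 29.3 ± 5.69 against 0.752 ± 0.268 CPM and Rsad2, which encodes the antiviral protein viperin, at 31.7 ± 16.7 against 0.870 ± 0.320 CPM.

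Single genes of large change in basal cells began with a, the agouti gene of coat pigment signalling (gene 50518, chromosome 2, 154950599 to 155051012), with 528 ± 44.8 CPM in KO and 2 counts in all 3 WT libraries. The ratio of pooled counts was 15366 (95% counting interval 4253.5 to 126890). Among the other genes of largest rise were Kif18b, Pclaf, Cenpf, Neil3 and Ccnb1, which act in mitosis or DNA replication and repair. Cenpf stood at 36.9 ± 22.2 against 0.421 ± 0.288 CPM and Pclaf at 15.4 ± 9.02 against 0.135 ± 0.160 CPM. Aurkb, the Aurora B kinase, had 1 count in WT and 571 in KO, a pooled ratio of 478 (95% counting interval 85.4 to 18909). Ccnb1 stood at 12.3 ± 7.40 against 0.177 ± 0.0938 CPM, and the division of its reads with its near-identical pseudogene Ccnb1-ps, which rose too, is uncertain. Cdkn2a, which encodes the p16 and p19 proteins of senescence, had 2 WT and 192 KO counts, a pooled ratio of 80.3 (95% counting interval 21.9 to 668). Among the falls, Kif27 stood at 1.73 ± 0.150 against 7.51 ± 4.35 CPM (log2 fold change -2.07, SE 0.38, adjusted p = 0.0027). C4b, complement component 4B, stood at 126 ± 45.1 against 479 ± 49.1 CPM (log2 fold change -1.92, SE 0.46, adjusted p = 0.024) and Foxj1, a regulator of motile cilia, at 25.7 ± 1.83 against 95.1 ± 71.9 CPM (adjusted p = 0.015). The call of C4b was lost in 5 of 14 other settings (adjusted p = 0.058 to 0.13 there and 0.0028 to 0.13 over all 14), each of them without 1 library (KO replicate 1 or 2, or any WT replicate). That of Foxj1 was lost in 4, namely in a fit of the 6 basal libraries and without KO replicate 2 or 3 or WT replicate 3 (adjusted p = 0.067 to 0.17 there and 5.5e-04 to 0.17 over all 14).

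Some repair and luminal genes were also higher in basal KO cells, in lists that passed with a fixed correlation but not with an estimated one. Luminal cells in the basal KO sort were not tested as a source of the luminal genes. Of 29 measured genes of homologous recombination and the Fanconi pathway 5 rose and 0 fell, 10 adjusted over the list alone (camera adjusted p = 5.0e-04; adjusted p = 0.51 with an estimated correlation). Brca1, which acts in the same repair pathway as Brca2, stood at 6.25 ± 3.73 against 0.952 ± 0.334 CPM (adjusted p = 0.029) and the Fanconi anemia gene Fanca at 3.99 ± 0.979 against 0.669 ± 0.259 CPM (adjusted p = 0.024). Both calls were lost in limma voom and without KO replicate 2 or any 1 WT replicate, that of Fanca also without KO replicate 3 (adjusted p over 14 settings 4.4e-04 to 0.23 and 2.0e-04 to 0.12). Of 19 luminal progenitor genes 3 rose and 0 fell, 9 adjusted over the list alone (camera adjusted p = 6.0e-06; adjusted p = 0.21 with an estimated correlation). Kit stood at 13.6 ± 6.74 against 2.16 ± 0.738 CPM (log2 fold change 2.71, SE 0.41, adjusted p = 3.7e-04) and the epithelial transcription factor Ehf at 18.8 ± 6.82 against 3.59 ± 1.32 CPM. Of 20 mature luminal genes 2 rose, 5 adjusted over the list alone with 1 lower (camera adjusted p = 0.0037; adjusted p = 0.39 with an estimated correlation). One of them was Areg, an epidermal growth factor receptor ligand, at 68.1 ± 5.11 against 6.98 ± 6.42 CPM (adjusted p = 7.7e-04). Among 14 luminal keratin and junction genes 3 rose, also 3 adjusted over the list alone, with the claudin Cldn7 at 8.47 ± 0.512 against 2.04 ± 0.115 CPM (camera adjusted p = 0.0056; adjusted p = 0.25 with an estimated correlation). Areg was also the 1 riser among 12 ErbB receptor and ligand genes, 4 adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.28 with an estimated correlation). It was the 1 riser among 11 estrogen and progesterone responsive genes, 2 adjusted over the list alone (camera adjusted p = 0.045; adjusted p = 0.44 with an estimated correlation, and 0.072 and 0.12 without KO or WT replicate 3).

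4 further lists shifted in basal cells with 0 members passing singly, over all genes or adjusted over the list alone. Milk and secretory genes (19 measured) lay higher, with a median log2 fold change of 1.09 (camera adjusted p = 0.0012; adjusted p = 0.57 with an estimated correlation). Cytosolic ribosomal proteins (76 measured), ribosome biogenesis (25) and immediate early genes (23) lay lower, with medians of -0.17, -0.26 and -0.36 and camera adjusted p of 0.0035, 0.0053 and 0.032. With an estimated correlation the adjusted p was 0.95 for each of these 3. The ribosomal protein call was lost without WT replicate 1 or 2 or KO replicate 3 (adjusted p = 0.47, 0.062 and 0.22), that of ribosome biogenesis without WT replicate 1 or KO replicate 3 (0.93 and 0.48) and that of immediate early genes without KO replicate 2 or WT replicate 2 or 3 (0.15, 0.57 and 0.65). Markers of immune cells had a median of -0.34, fibroblasts -0.04, endothelium and pericytes 0.33, adipocytes 0.21, and blood and muscle -0.85 (camera adjusted p = 0.55, 0.67, 0.58, 0.91 and 0.58), with 1 of 15 fibroblast markers rising and none of the others passing. In all, 519 genes changed in basal cells, 488 up and 31 down, out of 1912 at an unadjusted p under 0.05. In simulated unchanged libraries 49.8 genes on average lay under the same p-value, which is 9.6% of that count. 17.6% of all genes had no overlap between the genotypes, where chance gives 10%. The count was 345, 260 and 321 without WT replicates 1, 2 and 3, 338 and 341 without KO replicates 2 and 3, and 330 with libraries thinned to 1 depth. The 31 falls became 8 without KO replicate 2, and 10 and 11 without WT replicates 2 and 3.

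In LP cells, some cell division, interferon, energy and protein turnover genes differed between KO and WT. Their lists passed with a fixed correlation but not with an estimated one. They were not tested with per-library trends on GC content and length removed. Cdk1 stood at 55.7 ± 0.748 against 4.82 ± 0.445 CPM (log2 fold change 3.52, SE 0.33, adjusted p = 3.2e-06) and Cdc20, an activator of the anaphase-promoting complex, at 72.5 ± 11.2 against 4.98 ± 3.80 CPM. Of 36 cell cycle genes 25 rose and 0 fell, 26 adjusted over the list alone (camera adjusted p = 1.4e-27; adjusted p = 0.11 with an estimated correlation). Of 34 interferon genes 27 rose and 0 fell, 29 adjusted over the list alone (camera adjusted p = 1.3e-30; adjusted p = 0.18 with an estimated correlation). The oligoadenylate synthetases Oas1a, Oas2 and Oas3 stood at 62.9 ± 35.6 against 1.19 ± 0.0724 CPM, 126 ± 50.9 against 3.17 ± 0.924 CPM and 40.5 ± 13.4 against 0.973 ± 0.638 CPM, with log2 fold changes of 5.74, 5.27 and 5.29 (SE 0.59, 0.55 and 0.53). Oxidative phosphorylation genes went 39 up and 1 down of 74, 51 and 1 adjusted over the list alone (camera adjusted p = 2.0e-15; adjusted p = 0.39 with an estimated correlation). Ndufa4, an electron transport subunit, stood at 246 ± 68.4 against 75.3 ± 5.003 CPM (log2 fold change 1.71, SE 0.24, adjusted p = 1.1e-04). Of 31 proteasome subunits 18 rose and 0 fell, 21 adjusted over the list alone, with Psma7 at 242 ± 76.98 against 90.7 ± 20.9 CPM (camera adjusted p = 5.0e-10; adjusted p = 0.38 with an estimated correlation). Of 17 glycolysis genes 4 rose, 5 adjusted over the list alone, with the enolase Eno1 at 199 ± 52.7 against 49.001 ± 13.9 CPM (camera adjusted p = 0.040; adjusted p = 0.44 with an estimated correlation, and 0.073, 0.11 and 0.094 without WT replicate 2 or 3 or KO replicate 3). The 60 genes linked to mTORC1 went 11 up and 1 down, 11 and 2 adjusted over the list alone, without passing as a list (camera adjusted p = 0.058).

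Some of the genes that p53 activates fell in LP, as did some mature luminal and immediate early genes, in lists that passed with a fixed correlation but not with an estimated one. Of 28 p53 targets 7 fell and 2 rose, 11 and 4 adjusted over the list alone (camera adjusted p = 0.0080; adjusted p = 0.38 with an estimated correlation). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, stood at 135 ± 28.999 against 446 ± 197 CPM (log2 fold change -1.72, SE 0.35, adjusted p = 0.0034) and Trp53inp1 at 56.6 ± 15.05 against 327 ± 177 CPM (log2 fold change -2.53, SE 0.45, adjusted p = 0.0011). Pmaip1, which encodes the cell death protein Noxa, went the other way, at 41.05 ± 13.8 against 6.43 ± 2.69 CPM. In basal and ML cells the 28 p53 targets did not shift as a list: 2 rose and 0 fell in basal cells, 2 and 1 adjusted over the list alone, while 3 rose and 1 fell in ML, 7 and 2 adjusted over the list alone (camera adjusted p = 0.67 and 0.97). Their medians there were -0.05 and -0.05 and their means 0.15 and 0.27, so median and mean differed in sign. Of 20 mature luminal genes 6 fell and 0 rose in LP, 8 adjusted over the list alone (camera adjusted p = 0.0026; adjusted p = 0.38 with an estimated correlation), among them the estrogen receptor gene Esr1 at 5.96 ± 4.77 against 26.9 ± 8.49 CPM (log2 fold change -2.15, SE 0.43). These genes also mark ML cells, and whether the LP KO sort held fewer ML cells than the LP WT sort was not tested. Of 23 immediate early genes, which also respond to tissue dissociation, 7 fell and 0 rose, 12 adjusted over the list alone (camera adjusted p = 4.4e-08; adjusted p = 0.38 with an estimated correlation). Fos stood at 1688 ± 358 against 6783 ± 2711 CPM and Fosb at 1018 ± 205 against 7808 ± 4377 CPM.

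The LP genes of largest rise included 3 with 0 counts in all WT libraries. Against a floor of 3 counts over the group, Atp6v0a4, a proton pump subunit, was at least 59.5-fold higher in KO, Crb1 at least 51.6-fold and Scrg1 at least 46.8-fold. Stra6, a receptor for vitamin A uptake, stood at 78.4 ± 71.8 against 0.258 ± 0.278 CPM. Alox5ap and Runx3 had 2 WT counts each, with pooled ratios of 253 and 118 (95% counting intervals 69.8 to 2088 and 32.5 to 976). Cdkn2a also had 2 WT counts, with a ratio of 100.4 (95% counting interval 27.7 to 831). The agouti gene a stood at 359 ± 202 CPM in KO with 6 WT counts, a pooled ratio of 2022 (95% counting interval 929 to 5511). Among the falls, the surface peptidase Mme stood at 25.04 ± 10.8 against 256 ± 71.6 CPM (log2 fold change -3.35, SE 0.35, adjusted p = 9.5e-06), the glypican Gpc6 at 6.31 ± 2.91 against 68.4 ± 39.8 CPM, the collagen Col8a1 at 5.53 ± 3.62 against 69.2 ± 20.5 CPM and the transcription factor Dach1 at 1.16 ± 0.191 against 13.5 ± 6.71 CPM.

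Some immune cell markers were higher in LP KO. Of 14 measured, 7 rose and 0 fell, 12 adjusted over the list alone (camera adjusted p = 8.9e-04; adjusted p = 0.44 with an estimated correlation). Cd74, the invariant chain of antigen presentation, stood at 112 ± 80.7 against 5.93 ± 0.547 CPM and lost its call without WT replicate 2 (adjusted p = 0.053, range over 14 settings 7.7e-05 to 0.053). The macrophage receptor Csf1r stood at 4.74 ± 2.76 against 0.762 ± 0.508 CPM and lost its call in a fit of the 6 LP libraries (adjusted p = 0.057, range 5.1e-04 to 0.057). The immune list had a median log2 fold change of 3.29, or 3.21 with 1 member of 0 WT counts set at its floor. Medians for fibroblasts, endothelium and pericytes, adipocytes, and blood and muscle were 0.99, 0.22, 0.04 and 1.41 (camera adjusted p = 0.47, 0.66, 0.97 and 0.15), with 1 of 7 blood and muscle markers rising and 0 members of these other lists passing. In all, 2456 genes changed in LP, 1364 up and 1092 down, out of 5018 at an unadjusted p under 0.05. 31% of all genes had no overlap between the genotypes, where chance gives 10%. A fit of the 6 LP libraries alone called 788 genes, and the count was 1012 without WT replicate 2, 1631 without KO replicate 1 and 1477 without KO replicate 3. The 1092 falls became 254 in the 6 LP libraries and 417 without WT replicate 2. With per-library trends on GC content and length removed, 2106 genes were called, 1669 of them among the 2456. The gene lists were not tested with those trends removed.

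In ML cells, KO libraries carried basal and luminal progenitor transcripts that were scarce in WT, and some mature luminal genes were lower. Krt14, a basal keratin, stood at 262 ± 40.6 against 3.84 ± 2.71 CPM (log2 fold change 6.26, SE 0.55, adjusted p = 1.6e-07) and Krt5 at 157 ± 23.4 against 2.64 ± 0.788 CPM (log2 fold change 5.99, SE 0.40, adjusted p = 4.8e-09). Col17a1, a hemidesmosome collagen, stood at 89.8 ± 18.9 against 0.541 ± 0.217 CPM. Of 22 basal identity genes 18 rose and 0 fell, 19 adjusted over the list alone (camera adjusted p = 1.6e-32; adjusted p = 1.5e-04 with an estimated correlation). Of 19 luminal progenitor genes 14 rose and 1 fell, 15 and 1 adjusted over the list alone (camera adjusted p = 1.1e-09; adjusted p = 0.046 with an estimated correlation). Kit stood at 184 ± 66.5 against 11.8 ± 1.37 CPM (log2 fold change 3.95, SE 0.39, adjusted p = 6.7e-07) and the transcription factor Sox10 at 87.8 ± 43.8 against 3.43 ± 0.585 CPM. Of 20 mature luminal genes 7 fell and 0 rose, 11 adjusted over the list alone (camera adjusted p = 4.3e-05; adjusted p = 0.11 with an estimated correlation). Cited1 stood at 195 ± 81.5 against 669.9 ± 154 CPM (adjusted p = 0.0059) and Esr1 at 80.2 ± 30.1 against 231 ± 56.5 CPM (adjusted p = 0.014), of which Esr1 lost its call without KO replicate 1 and without WT replicate 2 (adjusted p up to 0.083, range over 14 settings 0.0047 to 0.083).

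Basal genes reached different shares of their basal level in ML KO. Shares are the excess over the mean ML WT level, as a percentage of the mean basal KO level after the same subtraction. Krt5, Krt14, Krt17 and Trp63 had shares between 6.33% and 13.5% in the 3 ML KO libraries. The contractile genes Acta2, Myh11, Cnn1, Tagln and Mylk had mean shares of 0.495%, 0.358%, 0.134%, 0.896% and 2.16%. The subtraction weighs most on small shares. Cnn1 stood at 1.79 CPM in ML KO and 1.09 CPM in ML WT, beside 519 CPM in basal KO. Other basal genes lay within this whole range, such as Sparc at 1.59%, Oxtr at 2.29%, Cdh3 at 4.69% and Lama3 at 5.41%. Across 200 genes restricted to basal cells the median was 5.10% (quartiles 2.77% and 8.21%). Acta2, smooth muscle actin, stood at 26.6 ± 5.28 against 4.07 ± 1.89 CPM in ML beside 4553 ± 41.7 CPM in basal KO. Across 47 genes restricted to LP (at least 50 CPM in LP KO), the median ML KO share of the LP KO level, reckoned in the same way, was 25.8% (quartiles 21.1% and 33.2%). It was 47.4%, 10.8% and 19.4% in ML KO replicates 1, 2 and 3, and 76 genes restricted to ML kept a median of 21.3%, 45.8% and 56.6% of their ML WT level in the same libraries. Restricted genes were chosen from KO levels and the ML WT level in these same data, without LP WT. Genes higher in KO in both LP and ML can thus enter the LP set, and the ML set can favour genes lower in KO. Without KO replicate 1 the progenitor and mature luminal lists still passed (camera adjusted p = 6.2e-09 and 3.1e-04).

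**Figure D2:**
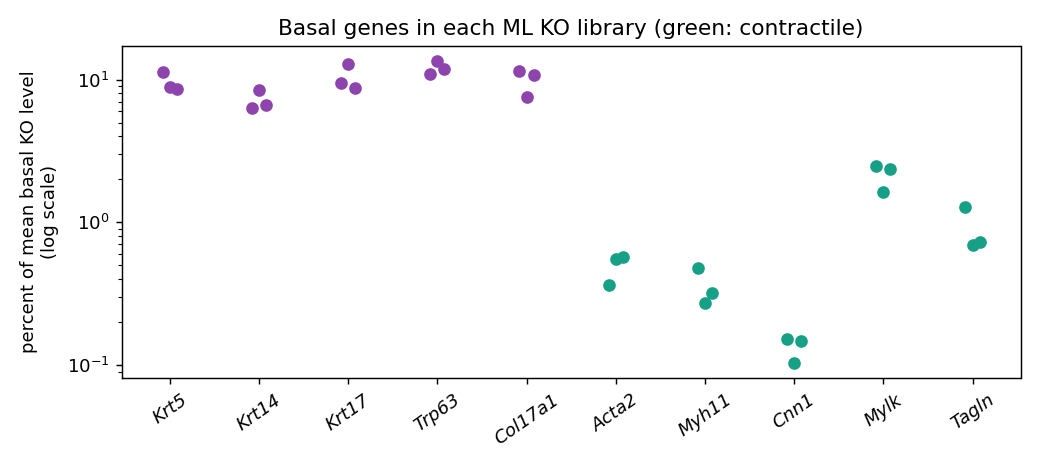
Share of 10 basal genes in each of the 3 ML KO libraries (log axis). Shares are the excess over the mean ML WT level, as a percent of the mean basal KO level after the same subtraction. Keratins, Trp63 and Col17a1 (purple) lie between 6.33% and 13.5%, and contractile genes (green) at or below 2.49%. 9 further basal genes are not drawn, with means from 1.59% for Sparc to 8.74% for Id4.

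Part of the signalling and matrix genes rose in ML KO as well. Cells of other gates in the ML KO sort, weighed later, were not separated from these rises. Of 21 Wnt pathway genes 11 rose and 1 fell, 12 and 1 adjusted over the list alone (camera adjusted p = 1.1e-09; adjusted p = 2.1e-04 with an estimated correlation), with the stem cell receptor Lgr5 at 15.6 ± 6.97 against 0.183 ± 0.161 CPM (log2 fold change 6.03, SE 0.56) and the Wnt antagonist Nkd2 at 58.8 ± 17.2 against 0.241 ± 0.285 CPM. Of 29 extracellular matrix and epithelial-mesenchymal transition genes 17 rose and 0 fell, 18 adjusted over the list alone (camera adjusted p = 8.8e-12; adjusted p = 2.1e-04 with an estimated correlation). The matricellular genes Ccn2 and Thbs1 stood at 212 ± 112 against 2.78 ± 1.21 CPM and 1206 ± 711 against 37.6 ± 17.2 CPM. Of 14 senescence genes 8 rose, also 8 adjusted over the list alone (camera adjusted p = 3.1e-06; adjusted p = 0.0016 with an estimated correlation). Igfbp3 stood at 64.9 ± 13.8 against 0.933 ± 0.404 CPM, Cdkn2a at 12.1 ± 5.55 against 0.959 ± 0.922 CPM and Lmnb1, the lamin B1 gene that is lower in senescent cells, at 74.4 ± 25.3 against 17.97 ± 2.45 CPM. Of 23 NF-kB and inflammation genes 11 rose and 0 fell, 12 adjusted over the list alone, with Tnf at 42.98 ± 24.97 against 5.27 ± 3.40 CPM (camera adjusted p = 3.9e-06; adjusted p = 0.24 with an estimated correlation). Of 16 Notch pathway genes 8 rose and 0 fell, 9 and 1 adjusted over the list alone, with the ligand gene Dll1 at 16.7 ± 3.59 against 1.02 ± 1.04 CPM (camera adjusted p = 0.016; adjusted p = 0.054 with an estimated correlation). Of 19 milk and secretory genes 6 rose and 0 fell, 12 adjusted over the list alone, with the xanthine dehydrogenase gene Xdh at 81.8 ± 36.5 against 12.8 ± 4.92 CPM (camera adjusted p = 1.3e-04; adjusted p = 0.44 with an estimated correlation).

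Cell division and interferon genes rose in ML as in the other populations. Of 36 cell cycle genes 27 rose and 0 fell, 29 adjusted over the list alone (camera adjusted p = 4.1e-25; adjusted p = 0.042 with an estimated correlation), with Bub1 at 15.4 ± 3.28 against 0.361 ± 0.213 CPM (log2 fold change 5.30, SE 0.50). Of 34 interferon genes 21 rose and 0 fell, 23 adjusted over the list alone (camera adjusted p = 1.3e-10; adjusted p = 0.39 with an estimated correlation), with Cxcl10 at 61.2 ± 9.14 against 3.97 ± 3.16 CPM. Of 25 ribosome biogenesis genes 3 rose, also 3 adjusted over the list alone, among them Rrs1 at 54.9 ± 9.07 against 22.6 ± 3.50 CPM (camera adjusted p = 0.040; adjusted p = 0.88 with an estimated correlation, and 0.16, 0.056, 0.051 and 0.13 without KO replicate 1 or 2 or WT replicate 1 or 3). Lysosome and autophagy genes (29 measured) lay lower with 0 passing singly, over all genes or adjusted over the list alone (median -0.17, camera adjusted p = 0.040; adjusted p = 0.44 with an estimated correlation, and 0.082 and 0.089 without WT replicate 1 or KO replicate 2). Dsc3, a desmosome cadherin of stratified epithelia, had 0 counts in ML WT and 64.9 ± 5.49 CPM in KO, at least 889-fold higher. Gfra1, Slc4a4 and Scel also had 0 WT counts and were at least 163-, 112- and 113-fold higher. The agouti gene a stood at 181 ± 73.2 CPM with 5 WT counts, a pooled ratio of 1295 (95% counting interval 555 to 3990). Among the falls, the adrenergic receptor Adra1a stood at 15.9 ± 2.78 against 75.4 ± 36.4 CPM (log2 fold change -2.26, SE 0.35, adjusted p = 5.2e-05), the cadherin Cdh13 at 4.08 ± 1.90 against 28.7 ± 19.3 CPM and Napsa at 0.424 ± 0.597 against 5.71 ± 3.47 CPM.

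Markers of immune cells, fibroblasts, endothelium and pericytes, adipocytes, and blood and muscle had medians of 1.35, 1.33, 0.07, -0.43 and -0.25 in ML (camera adjusted p = 0.10, 0.12, 0.92, 0.97 and 0.50). Of 14 immune markers 3 rose and 0 fell, with 13 log2 fold changes above 0, and of 15 fibroblast markers 3 rose and 1 fell, with 14 above 0. Of 13 endothelial and pericyte markers 2 rose and 1 fell, of 9 adipocyte markers 1 rose (2 and 1 lower adjusted over the list alone), and of 7 blood and muscle markers 1 fell, with the other numbers unchanged when adjusted over each list alone. In all, 2511 genes changed in ML, 1935 up and 576 down, out of 4836 at an unadjusted p under 0.05. With per-library trends on GC content and length removed, the split was 1909 up and 1438 down. 37.8% of all genes had no overlap between the genotypes, where chance gives 10%. Without WT replicate 2 the count was 1622, with 1356 up and 266 down. The falls rested on single libraries more than the rises did, with 1509 up and 172 down without KO replicate 1, the library of highest LP share.

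**Figure D3:**
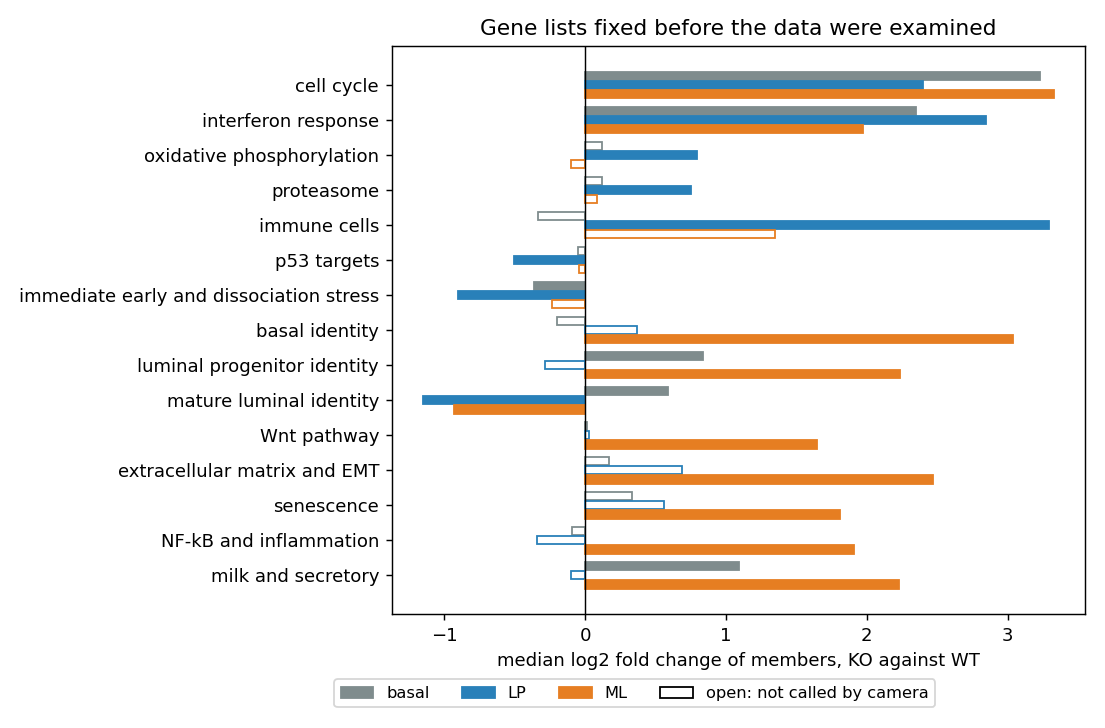
Median log2 fold change (KO against WT, horizontal axis) of the measured members of 15 gene lists in basal (grey), LP (blue) and ML (orange) cells; filled bars passed the camera test. The cell cycle medians are 3.23, 2.40 and 3.33, and the basal identity median is 3.04 in ML.

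The genes that changed overlapped between populations. Of the genes that rose, 235 were shared by basal cells and LP, 294 by basal cells and ML, and 504 by LP and ML, where independent lists of those sizes would share 40.4, 57.3 and 160. Of those that fell, 8, 7 and 135 were shared, against 2.06, 1.08 and 38.2. 182 genes rose and 4 fell in all 3 populations. The populations of 1 genotype came from the same 3 mice, which the figure for independent lists leaves out.

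Whether the genotype effect differed between populations was tested as an interaction. Between LP and ML it differed for 1049 genes, with 848 lower and 201 higher in LP relative to ML (1814 with the mouse as a block). Lama3, a laminin chain of the basement membrane, stood at 18.8 ± 6.62 against 143 ± 46.3 CPM in LP but 61.5 ± 18.99 against 5.26 ± 1.06 CPM in ML (log2 difference -6.46, SE 0.49, adjusted p = 2.1e-07). Col9a3 stood at 78.7 ± 27.3 against 69.1 ± 4.02 CPM in LP and 76.3 ± 11.98 against 1.67 ± 0.298 CPM in ML. Between ML and basal cells 910 genes differed, 741 of them higher in ML (1480 with the mouse as a block). The semaphorin Sema6a stood at 20.8 ± 2.23 against 0.232 ± 0.0956 CPM in ML and 62.4 ± 16.01 against 52.7 ± 5.93 CPM in basal cells (log2 difference 6.44, SE 0.46, adjusted p = 1.8e-08). Cells of other gates in the ML KO sort, weighed later, could also give such differences in the interactions that involve ML. Between LP and basal cells 180 genes differed, 64 higher and 116 lower in LP (491 with the mouse as a block). The small heat shock protein gene Hspb8 stood at 137 ± 53.5 against 4.11 ± 0.693 CPM in LP and 228 ± 22 against 188 ± 66.3 CPM in basal cells (log2 difference 4.80, SE 0.48, adjusted p = 6.2e-05), while Wee1, an inhibitor of entry into mitosis, stood at 69.98 ± 13.95 against 205 ± 50.6 CPM and 73.6 ± 1.01 against 47.1 ± 6.31 CPM (log2 difference -2.19, SE 0.31, adjusted p = 0.0018). Without WT mouse 2 the counts were 511 for LP against ML, 509 for ML against basal cells and 30 for LP against basal cells. They were 641 for LP against ML without KO mouse 1, and 110 and 50 for LP against basal cells without KO mice 2 and 3.

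As lists, basal identity genes differed most clearly in the interactions that involve ML. Of 22, 14 differed between LP and ML (18 adjusted over the list alone) and 16 between ML and basal cells (19 adjusted over the list alone), each with the higher genotype effect in ML (camera adjusted p = 9.8e-29 and 1.4e-39; adjusted p = 1.8e-04 and 5.3e-05 with an estimated correlation). Of 21 Wnt pathway genes 7 had a lower genotype effect in LP than in ML and 9 a higher one in ML than in basal cells, 9 and 12 adjusted over the list alone with 1 the other way in each (camera adjusted p = 1.1e-07 and 1.0e-10; adjusted p = 0.0022 and 1.4e-04 with an estimated correlation). Oxidative phosphorylation genes had a higher genotype effect in LP than in ML, 12 of 74 by single test and 37 adjusted over the list alone (camera adjusted p = 2.1e-16; adjusted p = 0.35 with an estimated correlation). The p53 targets had a lower genotype effect in LP than in basal cells, 2 of 28 by single test and 7 adjusted over the list alone (camera adjusted p = 9.0e-04; adjusted p = 0.23 with an estimated correlation).

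Gene positions were examined after the values had been seen. Relative to the autosomal median, the 911 measured genes of chromosome 11, which carries Trp53, had a median log2 shift of -0.20 in basal, -0.21 in LP and -0.20 in ML KO cells. Single libraries were measured against the mean of their population's WT libraries, which draws the WT values towards 0. By this measure KO libraries lay between -0.29 and -0.11 and WT libraries between -0.01 and 0.04. Of 10000 random gene lists of the same size and matched expression, 0 lay as far from 0 in each population. These lists drew single genes from all autosomes, which leaves out that genes of 1 chromosome can shift together. They cannot show that chromosome 11 differs from other chromosomes. Chromosome 11 was not alone. Genes of chromosome 12 lay lower in KO, with medians of -0.13 in basal cells, -0.31 in LP and -0.13 in ML, and those of chromosome 5 higher, with 0.09, 0.25 and 0.16. KO and WT libraries did not overlap in any of these by that measure, although for chromosome 12 in basal cells they all but met at -0.08. Lack of overlap was common and not particular to these chromosomes. Examples are chromosome 1 in basal cells and ML (medians 0.11 and 0.11), but not in LP, and chromosome 2 in LP (0.09). In LP and ML it also held for chromosomes 3 (0.16 and 0.19) and 19 (0.19 and 0.13), among others. It therefore does not mark chromosomes 11, 12 or 5 as unusual. In LP the genes of chromosome 7 lay furthest from 0, with a median of -0.41, or -0.53 with GC content and length trends removed. Chromosomes 5 and 12 lay further from 0 than chromosome 11 there, but not with those trends removed (0.20 and -0.23 beside -0.24). Chromosomes 4, 10, 17 and 19 stood at 0.19, -0.19, 0.18 and 0.19 there, and chromosome 3 at 0.19 in ML. Random lists were drawn for chromosome 11 alone.

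**Figure D4:**
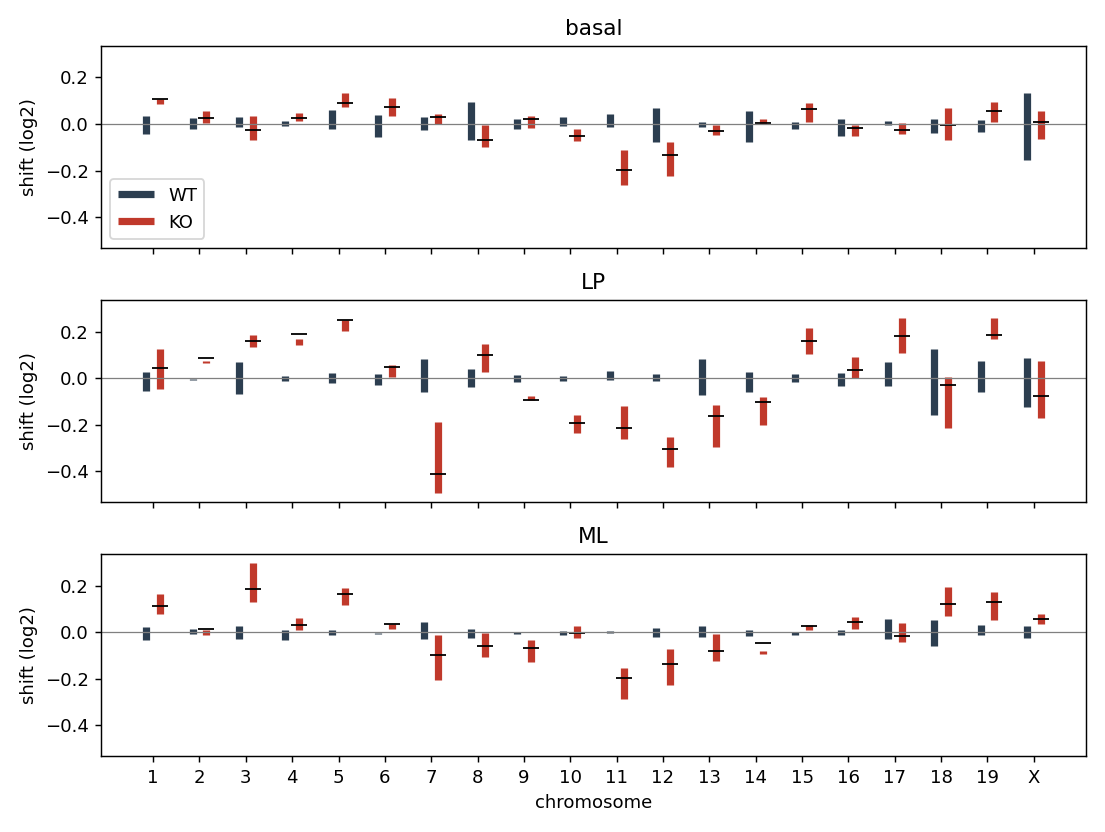
Median log2 shift of the genes of each chromosome against the autosomal median, by population. Bars span the 3 WT (dark) and 3 KO (red) libraries, each measured against the mean of the WT libraries, and black marks the KO against WT shift. Chromosome 11 lies between -0.29 and -0.11 in KO libraries of all 3 populations.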

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

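The interaction contrasts were fixed before the data were examined. The tests of GC content and length, depth and other splits of the samples were fixed before their results were seen. The remaining tests in this part were chosen after.

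The effect of genotype differed between populations by a test of the difference itself for 180 genes between LP and basal cells, 1049 between LP and ML and 910 between ML and basal cells. Between LP and basal cells the log2 differences of the 5 genes of lowest p were 4.80 for Hspb8, 5.22 for Nkd2, -4.15 for Egflam, -2.19 for Wee1 and -3.61 for Cpe. Between LP and ML they were -5.86 for Sema6a, -6.46 for Lama3, -6.89 for Col17a1, -5.31 for Col9a3 and -9.67 for Lgr5, and -2.03 for the targeted gene Trp53. Between ML and basal cells they were 6.44 for Sema6a, 7.06 for Col17a1, 7.16 for Col14a1, 6.85 for Ccn2 and 7.24 for Wif1. The interactions that involve ML include basal genes that were scarce in ML WT, such as Col17a1. Cells of other gates in the ML KO sort, weighed below, could give such differences and were not separated from a genotype response.

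Basal and LP transcripts in the ML KO libraries were weighed against cells of other gates; basal cells of average composition would bring contractile and keratin genes in the same proportion. Mylk reached a share of 2.49% of its basal KO level, with the ML WT level subtracted from both. This lay above the 2.11% that had been set as the bound, so this gene leaves that source open. Taken as a set, a test chosen after the bound was missed, the contractile genes had a library median share of at most 0.572%. Keratin and Trp63 shares, reckoned with the same subtraction, were 6.33% or more. The keratin and Trp63 shares thus lay above every contractile share. Other basal genes bridged the gap, with mean shares from 1.59% for Sparc through 4.69% for Cdh3 to 9.98% for Col17a1. As the set test was also chosen after the bound was missed, it cannot decide the source of the keratins. Basal cells of average composition stay open, and basal cells poor in contractile genes may also contribute. LP cells in the ML gate may contribute to the LP genes and stay open, with up to 25.5% of 47 LP-restricted genes (replicate 2; 14.9% and 10.6% in replicates 1 and 3) below 50% of their library's median share. As the whole cause of lower mature luminal genes they fall short at the median by these shares, where ML-restricted genes kept 21.3%, 45.8% and 56.6% of the WT level beside LP shares of 47.4%, 10.8% and 19.4%. The gap exceeded the spread of genes in replicates 1 and 2 only (upper quartiles of 29.3% and 60.6% where 41.6% and 81.5% would be left, but 75.5% where 73.0% would be in replicate 3). Both gene sets were chosen from levels in these same data, without LP WT, and the choice can favour ML-restricted genes that are lower in KO. The shares therefore cannot decide it. LP cells as the whole cause stay open, as does a change of identity with genotype, which was not tested.

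Chromosome 11 genes and Trp53 were lower in KO in all 3 populations, as were chromosome 12 genes, while chromosome 5 genes were higher, and in LP chromosome 7 shifted further than chromosome 11 (-0.41, or -0.53 with GC content and length trends removed). After GC content and length trends were removed, at least 99.6% of the chromosome 11 shift was left in each population, which argues against these trends as its source. After thinning at least 87.8% was left. Thinning keeps the expected ratios between libraries, so it speaks only to the number of reads counted. It cannot exclude another bias that goes with depth. Loss of 1 Trp53 copy alone cannot be the whole fall of Trp53 in LP, where the log2 change plus 2 standard errors was -2.89. Loss of chromosome 11 copies in a share of cells could give the shift of -0.21 in LP, but these counts hold no measure of copy number. Strain background, which goes with genotype here, stays open too.

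Gene a was high in each KO library and at 2 to 6 counts per WT group. A strain or transgene variant at the locus may be the source, and in that case neighbouring genes could differ as well. Of 38 tested genes within 1 Mb, 0 changed in all 3 populations, while 12 (31.6%) changed in at least 1, beside 26.6% of all genes. Among all 16466 genes only 182 rose and 4 fell in all 3 populations, so 0 of 38 does not speak against such a variant. Strain background and genotype cannot be told apart in this design, and the effect of the deletion itself on a was not tested.

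Other splits into 3 and 3 were counted, of the 6 libraries for KO against WT and between WT populations, and of the 6 mice for the interactions. The WT populations come from the same 3 mice, and 4 of the 10 splits, the real one included, put all 3 mice in both parts. In each of the 9 comparisons 1 of 10 splits, the real one, gave as many genes. 10 splits cannot give a share under 0.05 (never under 0.1). Each other split also mixes the compared groups within its parts, which puts any real difference into the spread of the fit. Low counts there do not show what groups without a difference would give. For KO against WT the real counts were 519, 2456 and 2511 in basal, LP and ML, and the highest of the other splits 2, 5 and 1. For the interactions they were 180, 1049 and 910, and the highest other 0, 0 and 0. For the WT populations they were 6106 (LP against basal), 5548 (LP against ML) and 8981 (ML against basal), and the highest other 4, 1 and 0, or 0, 1 and 0 where all 3 mice were in both parts.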

How the results depend on the processing

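Thinning, the removal of GC content and length trends, and the settings for the Trp53 interactions were chosen after seeing the data, and all other settings were fixed earlier. The causes of the differences below were not tested, unless a setting uses fewer libraries or reads. Trp53 kept its direction and its call in each population under every setting tried. The 5 genes of lowest p of each interaction and the genes named between WT populations (96 of 96 values per contrast) kept their call and direction. For Trp53, LP against ML lost its call without WT mouse 3 (adjusted p = 0.085, range 9.3e-04 to 0.085), LP against basal cells (range 0.0084 to 0.19) passed in 5 of 11 settings, the mouse block (pairing) among them, and ML against basal cells, never called, changed sign without KO mouse 3 (-0.20) and WT mouse 3 (-0.05); the cause was not tested. Among named genes, 467 of 558 values in basal cells, 749 of 779 in LP and 926 of 966 in ML kept call and direction, and 91, 29 and 37 lost the call. Brca2, never called, changed sign in ML without WT replicate 1 (-0.08), without KO replicate 2 (-0.16) and with GC content and length trends removed (-0.016; -0.16 to 0.80 over single left-out libraries), and in LP with those trends removed (0.013); the cause was not tested.

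Some counts moved by over 1.5 times. The interactions LP against basal, LP against ML and ML against basal gave 532, 1722 and 1414 genes in DESeq2 (180, 1049 and 910 in edgeR), and 274 and 1575 for the first 2 in limma voom. With the mouse as a replicate block (pairing the populations of a mouse) they were 491, 1814 and 1480, and the WT contrasts moved less, to 7006 (LP against basal), 6556 (LP against ML) and 9608 (ML against basal). Across genotypes, where a number is shared by different mice, the replicate block moved total counts by less than 1.5 times, to 609, 3303 and 3168 genes for basal, LP and ML. The falls moved further in basal cells (31 to 58) and in ML (576 to 965). Same-numbered libraries correlated over 0.1 in 4 of 9 pairs. LP alone gave 788 genes, and thinned basal libraries 330, which is what depth limits there. Leaving out 1 library gave 260 to 505 genes in basal cells, 1012 to 2558 in LP and 1622 to 2351 in ML. Leaving out 1 mouse gave 30 to 132, 511 to 833 and 509 to 843 for the interactions in the order above, and 3973 to 5333, 3443 to 4155 and 6753 to 7887 for LP against basal, LP against ML and ML against basal in WT. RLE scaling moved the median of all genes to -0.11 (from -0.07) in the interaction of LP and ML and to -0.14 (from -0.07) in WT ML against basal cells.

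List calls were lost most often with an estimated correlation. In basal cells the adjusted p was then 0.51 for homologous recombination, 0.95 for cytosolic ribosomal proteins, ribosome biogenesis and immediate early genes, 0.21 for luminal progenitor and 0.39 for mature luminal identity, 0.25 for luminal keratins, 0.57 for milk, 0.44 for estrogen and progesterone responsive and 0.28 for ErbB genes. In LP it was 0.38 for p53 targets, proteasome, immediate early and mature luminal genes, 0.11 for cell cycle, 0.44 for glycolysis and immune cells, 0.39 for oxidative phosphorylation and 0.18 for interferon. In ML it was 0.88 for ribosome biogenesis, 0.44 for lysosome and for milk, 0.39 for interferon, 0.24 for NF-kB, 0.11 for mature luminal identity and 0.054 for Notch. With fry the adjusted p in basal cells was 0.10 for homologous recombination and for estrogen and progesterone responsive genes, 0.69 for cytosolic ribosomal proteins and immediate early genes, 0.62 for ribosome biogenesis, 0.075 for mature luminal identity and 0.24 for milk, and in ML 0.088 for ribosome biogenesis and 0.070 for lysosome. Estrogen and progesterone responsive genes in basal cells had 0.052 with RLE, 0.062 without the filter, 0.28 in voom and 0.19 in the 6 libraries. Immediate early genes in basal cells had 0.081 in voom and 0.095 in the 6 libraries, and mature luminal identity 0.087 in voom. In the 6 libraries glycolysis in LP had 0.094 and lysosome in ML 0.077 (0.059 thinned). Leaving out 1 library gave in basal cells 8.3e-11 to 0.47 for cytosolic ribosomal proteins, 4.4e-07 to 0.93 for ribosome biogenesis, 9.9e-10 to 0.65 for immediate early and 0.011 to 0.12 for estrogen and progesterone responsive genes, in LP 0.0093 to 0.11 for glycolysis, and in ML 0.0080 to 0.16 for ribosome biogenesis and 0.022 to 0.089 for lysosome. The lists were not tested in DESeq2 or with GC content and length trends removed.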

Other observations

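Some members of lists that did not pass changed in ML KO cells. Cells of other gates in the ML KO sort were not separated from these changes. Of 12 ErbB receptor and ligand genes 4 rose and 0 fell, 4 and 1 adjusted over the list alone (camera adjusted p = 0.21). Egfr, the epidermal growth factor receptor, stood at 47.4 ± 9.50 against 1.87 ± 1.02 CPM (log2 fold change 4.71, SE 0.38, edgeR adjusted p = 7.0e-08) and its ligand Ereg at 4.03 ± 0.555 against 0.354 ± 0.161 CPM. The fatty acid desaturases Fads1 and Fads2 stood at 71.2 ± 31.9 against 14.7 ± 3.18 CPM and 77.2 ± 29.01 against 10.5 ± 4.90 CPM (adjusted p = 7.0e-05 and 7.9e-06), among 17 fatty acid synthesis genes of which 4 rose and 0 fell, 4 and 1 adjusted over the list alone (camera adjusted p = 0.62). Of 16 hypoxia genes 3 rose and 1 fell, also 3 and 1 adjusted over the list alone, with the carbonic anhydrase Car9 at 2.40 ± 0.774 against 0.0977 ± 0.134 CPM (camera adjusted p = 0.62).

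Single genes of other lists that did not pass rose in LP and ML. Gsta3, a glutathione transferase, stood at 13.2 ± 6.42 against 0.258 ± 0.278 CPM in LP and 3.05 ± 2.73 against 0.171 ± 0.296 CPM in ML (adjusted p = 5.3e-05 and 0.0085), and Gstm1 at 36.6 ± 15.1 against 11.2 ± 1.13 CPM and 17.7 ± 7.50 against 6.60 ± 2.14 CPM. Of 17 NRF2 target genes 3 rose in LP and 4 in ML, with 0 falling and the same numbers adjusted over the list alone (camera adjusted p = 0.15 and 0.51). Psat1, an enzyme of serine synthesis, stood at 58.8 ± 29.9 against 5.15 ± 2.42 CPM in ML (adjusted p = 0.0018), among 22 ATF4 and amino acid response genes of which 3 rose and 2 fell, 5 and 2 adjusted over the list alone (camera adjusted p = 0.10). The repair gene Rad54l stood at 11.8 ± 2.76 against 3.17 ± 1.26 CPM in LP and 7.44 ± 2.56 against 1.92 ± 1.04 CPM in ML, where the homologous recombination list did not pass (4 up and 2 down of 29 in LP, 7 up and 1 down in ML, with 4 and 2 and 7 and 2 adjusted over the list alone; camera adjusted p = 0.45 and 0.50).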
